A study of Mus musculus with 52 samples.

How the data were processed

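RNA of mouse CD8+ T cells was measured by bulk MARS-seq, which sequences the 3′ ends of transcripts. Per the labels, the cells came from spleens of OT-I mice by magnetic sorting, and the dendritic cells (DCs) that activated some of them were CD11c-selected from C57BL/6 spleens. The labels name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 as tools and mm10 as the genome build. Whether reads of the same molecule were collapsed is not given, so counts may include copies of 1 molecule and counting error is a lower limit of the noise.

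The deposited table gives whole-number counts of 14626 genes in 52 libraries, with no normalization. Every gene reaches 6 counts in at least 1 library, so genes with fewer were left out by the authors under a rule that is not stated. The same deposited table holds log2 fold changes from the authors' DESeq2 fit for the 4 comparisons of coated with uncoated cells. It also holds the authors' adjusted p-value for each of these fold changes. The authors' values are printed only where they are named as such.

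Libraries fall into 9 groups by day, activation and coating. Their titles carry an M number from 1 to 10, used as the replicate, and DC titles carry 30 or 120; the labels explain neither number. Nothing states that M numbers are separate animals, so p-values measure the spread between these samples. The 16 DC libraries of day 3 were summed per M number and coating to 9 samples, since libraries with 1 M number and coating are not independent. Totals run from 382924 to 4641802 counts, and the 10 most abundant genes of a library take 5.9% to 15.9% of them. None of the 142 pairs of libraries compared was identical.

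For each of 14 comparisons, genes were filtered with filterByExpr (minimum count 10, minimum total 15) and scaled by TMM. They were tested with the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested. Only the groups compared entered a fit. A gene is called when its adjusted p is under 0.05. Differences between coating effects were tested as contrasts over 4 groups; for DC day 4 against day 3 the day 3 libraries were limited to those with 120 in the title, as at day 4. The comparison of 120 with 30 used single libraries with coating and M number in the fit. Values are CPM after TMM scaling, as mean ± SD with n samples. TMM factors were fitted within each comparison, so the CPM of a group can differ between comparisons. Sums over lists, values of single samples and the points of the expression figures use factors over all samples. Log2 fold changes carry their standard error (SE), taken from the fold change and its F statistic.

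Before the data were examined, the groups, comparisons, tests, alternatives, 29 gene lists (20 of functions, 9 of markers of cell types and of RNA quality) and the rule for named genes were fixed. The rule names up to 5 genes in each direction per coating comparison (up to 4 in the others) with the largest fold change among called genes with a mean of at least 20 CPM and groups that do not overlap. It adds up to 2 called genes with the smallest p from each list in the coating comparisons, and 10 genes in every comparison whatever their p. The overlap of groups has no meaning for the 3 differences of effects and was not asked of them. Gene models without a name and receptor segments were left out. Some results of named genes, included in the counts, are not reported here. Lists were tested with camera in limma 3.58.1, at the preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison, and with fry.

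Alternatives were size factors of DESeq2 in the same fit, no filter, the Wald test of DESeq2 1.42.0, all groups in 1 fit, M number as a block, single DC libraries, DC libraries with 30 or with 120 alone, and leaving out each sample in turn. Those added after the data were seen left out the library with the fewest counts, DC day 4 M number 8, uncoated bead day 7 M numbers 3 and 4, bead day 3 M number 2, the marker genes of other cell types (for the comparisons with day 0) and Gapdh (from the glycolysis list). Deviations from the group means of coated and uncoated libraries with 1 M number correlated above 0.1 in every pair only at DC day 4 (5 pairs, 0.13 to 0.34). The correlations ran from -0.18 to 0.49 at bead day 7, 0.07 to 0.23 at DC day 3 and 0 to 0.21 at bead day 3.

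The test was run on simulated counts with the depth, mean expression and dispersion of these libraries. A gene had the same dispersion in every sample, so the simulation holds no outlying libraries and its recovery may be too high. At a 2-fold change it recovered 46.9% of changed genes with the sample numbers of the bead comparison at day 3, 71.4% at day 7, 79.6% for DC day 3 and 90% for DC day 4. Positions are those of GENCODE vM21 for GRCm38, the assembly that mm10 names. Transcripts of near-identical genes (Gzmc and its neighbours, Mt1 and Mt2, Hba-a1 and Hba-a2, the histone genes) can be assigned to one another by short reads.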

Results

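The libraries hold RNA of CD8+ T cells whose OT-I receptor recognises a peptide of ovalbumin. Day 0 cells (9 libraries) were freshly isolated from spleen. The others had been activated by beads carrying antibodies against CD3 and CD28, with interleukin 2, or by DCs preloaded with the peptide. They grew in wells that were uncoated or coated with CCL21, a chemokine that guides T cells, and ICAM1, the ligand of the integrin LFA-1. Bead-activated cells were sampled at day 3 (5 coated and 3 uncoated libraries) and day 7 (4 and 5). DC-activated cells were sampled at day 3 (9 coated libraries of 5 M numbers and 7 uncoated ones of 4) and at day 4 (5 and 5). The series asks how the coating acts on proliferation and cytotoxicity after each kind of activation.

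Library totals were 733906 to 4641802 counts at day 0. Bead-activated cells had 1245996 to 2365135 counts (coated) and 630736 to 1617410 (uncoated) at day 3, and 1374720 to 1693377 and 1398853 to 2785011 at day 7. DC-activated cells had 382924 to 2876685 and 949327 to 4513513 at day 3, and 1430247 to 4348557 and 1140327 to 4455543 at day 4. The first principal component of the 1000 most variable genes carried 55.6% of their variance and the second 17.5%.

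**Figure D1:**
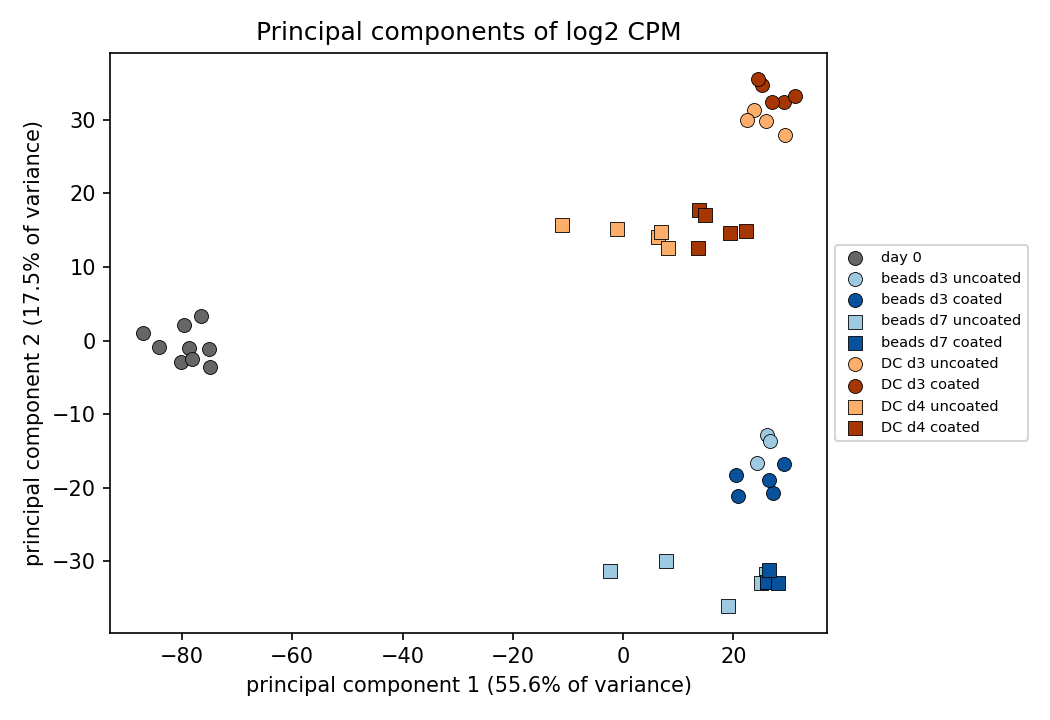
Principal components of the samples (x axis, component 1, 55.6% of the variance of 1000 genes; y axis, component 2, 17.5%); each point is 1 sample, coloured by group, with DC day 3 libraries summed per M number. Day 0 samples lie between -87.05 and -74.88 on component 1, and DC and bead samples part on component 2, DC samples lying at 12.59 or above and bead samples at -12.84 or below.

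DC-activated cells at day 4 on the coating held more transcripts of the granzymes Gzmb and Gzmc, of Ifng and of DNA replication genes, and fewer of genes of naive and memory T cells. Gzmb, which encodes the protease granzyme B of cytotoxic granules, had 1056 ± 649.7 CPM (SD, n = 5) in coated and 142 ± 14.7 CPM (n = 5) in uncoated cells. Its log2 fold change was 2.89 ± 0.47 (SE, adjusted p = 0.00618). Gzmc, another granzyme, rose by 3.16 ± 0.59 (adjusted p = 0.00897). Ifng, the cytokine interferon gamma, rose by 1.61 ± 0.36 (35.1 ± 18.9 against 12.1 ± 5.4 CPM, adjusted p = 0.0113), and Il2ra, the alpha chain of the interleukin 2 receptor, by 1.62 ± 0.42 (adjusted p = 0.025). Il2ra was low in uncoated cells, falling short of the filter when they were compared with day 0. Tcf7, a transcription factor of naive and memory T cells, fell by 1.98 ± 0.44 (214 ± 139 against 836 ± 131 CPM, adjusted p = 0.0185).

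Most genes of S phase rose at DC day 4. Of 37 tested genes of S phase, 32 rose and 0 fell (35 and 0 adjusted over the list alone). Among them were the replicative helicase subunit Mcm4 (226 ± 39.5 against 124 ± 8.29 CPM, log2 0.87) and the replication licensing factor Cdc6 (log2 0.96). The camera test gave an adjusted p of 8.71e-20 for this list (adjusted p = 0.19 with an estimated correlation). Of 40 genes of G2 and M phase, 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera 0.000347, adjusted p = 0.417 with an estimated correlation), with Hmgb2 at log2 0.82 and the mitotic kinase Plk1 at 0.54. The proliferation marker Mki67 had 341 ± 84.7 against 277 ± 57.8 CPM (log2 0.30 ± 0.19, adjusted p = 0.282).

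Among 20 genes of naive and memory cells at DC day 4, 13 fell and 0 rose (18 adjusted over the list alone; camera 2.44e-09, adjusted p = 0.358 with an estimated correlation). They included the interleukin 6 receptor Il6ra (log2 -2.44) and the transcription factor Klf3 (-2.09). Ccr7, the receptor of CCL21, fell by 1.28 ± 0.28 (192 ± 86.8 against 463 ± 40.9 CPM, adjusted p = 0.0124). Nsg2 had the most negative change of the named genes (log2 -3.02 ± 0.28, adjusted p = 0.000112).

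Cytotoxic effector genes went both ways at DC day 4. Of 14 tested, 4 rose and 2 fell (6 and 2 adjusted over the list alone), with a median log2 change of 0.03 and a mean of 0.59 (camera 0.275, adjusted p = 0.421 with an estimated correlation). Prf1, the pore-forming protein perforin, had log2 -0.14 ± 0.19 (adjusted p = 0.645). Prdm1, which encodes Blimp-1, a regulator of effector cells, rose by 2.18 ± 0.41 (adjusted p = 0.00314). Of 6 cytokine genes tested as a list, without Ifng, 1 rose, Csf1 by 1.15, and 1 fell, Ltb by 0.77 (1 and 1 adjusted over the list alone; camera 0.958, adjusted p = 0.99 with an estimated correlation). Among 15 genes of activation and costimulation 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera 0.177), with Il2rb at log2 0.78. The integrin subunit Itgal, part of the ICAM1 receptor LFA-1, had log2 0.09 ± 0.12 (adjusted p = 0.639). Of 28 genes of adhesion and integrin signalling, 7 fell and 2 rose (9 and 2 adjusted over the list alone; camera 0.0438, adjusted p = 0.417 with an estimated correlation), with P-selectin (Selp) at -2.18 and the actin crosslinker Actn1 at -1.22.

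Metabolic and stress genes also moved at DC day 4. Of 49 genes of oxidative phosphorylation 13 rose and 0 fell (14 adjusted over the list alone; camera 9.8e-05, adjusted p = 0.421 with an estimated correlation), with Cox5a at log2 0.76. Of 21 genes of cholesterol biosynthesis 6 rose and 0 fell (8 adjusted over the list alone; camera 0.00312, adjusted p = 0.358 with an estimated correlation), with Cyp51 at 0.95 and Sqle at 0.82. The unfolded protein response had 6 of 18 genes higher (7 adjusted over the list alone; camera 0.007, adjusted p = 0.421 with an estimated correlation), with the chaperone Hsp90b1 at 0.55. Of 20 glycolysis genes 4 rose, Ldha by 0.72, and 1 fell (5 and 2 adjusted over the list alone; camera 0.173). Of 22 interferon response genes 13 fell and 0 rose (15 and 3 adjusted over the list alone; camera 2.81e-05, adjusted p = 0.19 with an estimated correlation), with Stat2 at -0.96 and Irf7 at -1.03. Of 47 ribosomal protein genes 7 fell and 0 rose (3 adjusted over the list alone; camera 1.46e-05, adjusted p = 0.421 with an estimated correlation).

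Transcripts of other cells were higher in some uncoated libraries of DC day 4. The summed MHC class II transcripts were 569 ± 572 CPM in uncoated and 218 ± 84.7 CPM in coated cells. Uncoated M number 8 carries that mean with 1587.6 CPM, the other 4 having 314 ± 59.4 CPM. Of the 6 tested genes 2 fell, H2-Oa by 1.10 and H2-DMa by 0.52 (2 adjusted over the list alone; camera 0.0246, adjusted p = 0.421 with an estimated correlation). H2-DMa was not called with M number as a block (log2 -0.50, adjusted p = 0.0678, range over its alternatives 0.0279 to 0.18). Summed erythroid transcripts were 381 ± 518 against 128 ± 211 CPM, with 1189.5 CPM in uncoated M number 8 and 178 ± 291 CPM in the other 4. Of 12 CD8 T cell markers 2 fell, Trbc1 by 0.53 and Cd3e by 0.46 (1 adjusted over the list alone; camera 0.0173, adjusted p = 0.421 with an estimated correlation). Cd3e lost its call in 8 of 10 fits that left out 1 sample (highest adjusted p = 0.131).

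In all, 893 genes rose and 845 fell of 9159 tested at DC day 4, 76 and 202 of them by 2-fold or more. The authors' table calls 1519, of which 1253 are among these 1738 with the same direction. Libraries with 1 M number deviated together here, and with M number as a block 2572 genes were called, 1284 higher and 1288 lower. Of the 57 named genes called without the block, 46 passed whichever sample was left out. Without both libraries of M number 8, Tcf7 (log2 -1.89, adjusted p = 0.0571, range over its alternatives 0.000182 to 0.0571) and Ccr7 (log2 -1.20, adjusted p = 0.073, range 1.62e-05 to 0.073) missed the threshold. Il2ra missed it without coated M number 7 (adjusted p = 0.065, range 0.000354 to 0.065) or uncoated 6, 7 or 9. The count was 1082 without coated M number 6, 864 without coated 7, 1077 without uncoated 6 and 1145 without uncoated 10. With M number as a block, the inhibitory receptor Pdcd1 (log2 1.80 ± 0.54, adjusted p = 0.0509) had log2 1.58 and an adjusted p of 0.000251 (range 0.000251 to 0.113), and Mki67 log2 0.29 and 0.0204 (range 0.0204 to 0.719).

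**Figure D2:**
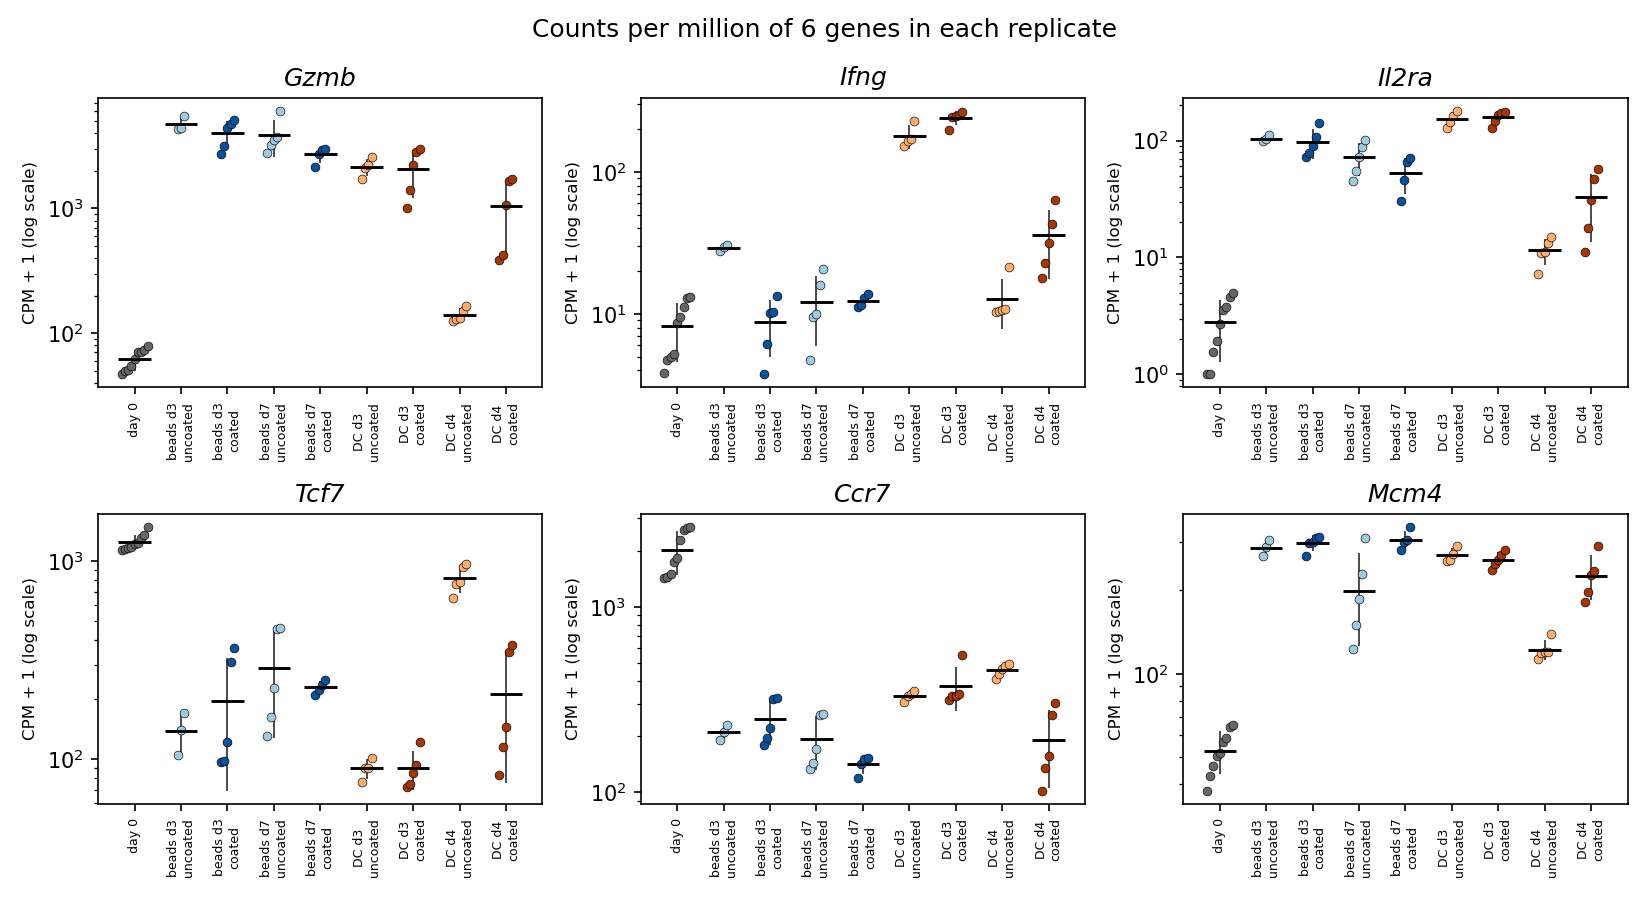
Expression of Gzmb, Ifng, Il2ra, Tcf7, Ccr7 and Mcm4 (y axis, CPM + 1, log axis) in each group (x axis); points are samples, horizontal lines means and vertical lines mean ± SD. At DC day 4 the mean of Gzmb is 1056 CPM in coated and 142 CPM in uncoated cells, and that of Tcf7 214 and 836 CPM.

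At DC day 3 fewer genes differed between coated and uncoated cells, and the genes with the smallest p were lower on the coating. Itgb7, an integrin subunit of gut-homing T cells, had 43.8 ± 3.02 CPM (SD, n = 5) in coated and 92.9 ± 14.9 CPM (n = 4) in uncoated cells (log2 -1.09 ± 0.11, adjusted p = 0.000635). Rasgrp2, an activator of the GTPase Rap1 in integrin signalling, fell by 1.45 ± 0.18 (adjusted p = 0.0031), and the Ras and Rap inhibitor Rasa3 by 0.97 ± 0.15 (adjusted p = 0.0112). Crip2 rose by 1.18 ± 0.21 (adjusted p = 0.0286), the costimulatory ligand Cd80 by 0.88 ± 0.16 (adjusted p = 0.0282) and the chemokine Ccl3 by 0.78 ± 0.14 (346 ± 32.1 against 200 ± 51.9 CPM, adjusted p = 0.0386).

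Of 25 tested interferon response genes at DC day 3, 3 fell and 0 rose (7 and 0 adjusted over the list alone; camera 1.69e-07, adjusted p = 0.199 with an estimated correlation), with Igtp at log2 -0.46. Of 19 p53 targets and apoptosis genes 2 rose, the pro-apoptotic Bax by 0.53 and Zmat3 by 0.66, and 0 fell (10 and 2 adjusted over the list alone; camera 0.000129, adjusted p = 0.199 with an estimated correlation). Of 21 glycolysis genes 2 fell, the glucose transporter Slc2a3 by 1.05 and Eno3 by 0.50 (5 adjusted over the list alone). The camera test gave this list an adjusted p of 0.000197 (adjusted p = 0.417 with an estimated correlation). Slc2a3 ran from log2 -1.15 to -0.39 over its 18 alternatives and was not called in 10. Eno3 ran from -0.56 to -0.30 and was not called in 11 of 18. Most glycolysis genes were also higher in libraries with the larger number in their title. Coated and uncoated sums mixed these libraries unequally, so the lower glycolysis genes are partly confounded with that number. None of 37 S phase genes was called (0 adjusted over the list alone; median -0.08, camera 0.0108, adjusted p = 0.344 with an estimated correlation), where 7 were positive. Ifng had log2 0.43 ± 0.14 (adjusted p = 0.197), and 0.41 with M number as a block (adjusted p = 0.0434, range over its alternatives 0.0309 to 0.82). Of 6 B cell markers 1 fell, Ighm by 0.41 (1 adjusted over the list alone; camera 0.0321, adjusted p = 0.371 with an estimated correlation), and summed mitochondrially encoded transcripts were 605 ± 485 against 347 ± 213 CPM.

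In all, 18 genes rose and 24 fell of 10245 tested at DC day 3; the authors' table calls 41, of which 17 are shared with the same direction. Gzmb had log2 -0.08 ± 0.32 (adjusted p = 0.938), but coated M number 3 has a library with 30 in its title and no other, and uncoated M number 3 one with 120. Other sums also mixed 30 and 120 unequally. For M number 4 the libraries with 120 and 30 had 382924 and 2184019 counts when coated, and 3070294 and 1411950 when uncoated. For M number 5 they had 1599458 and 2129429, against 4513513 and 1924134. Coated M number 2, without an uncoated match, had 2200553 and 1519549. The coating effect of DC day 3 is thus partly confounded with the 30 or 120 of the title for all genes. With that number as a covariate of single libraries Gzmb was at log2 0.72 (adjusted p = 0.0108, range over its alternatives 0.0108 to 0.998). Among libraries with 120 alone 8 genes were called and Itgb7 (log2 -0.54, adjusted p = 0.412, range 3.95e-11 to 0.412) and Rasgrp2 (log2 -0.63, adjusted p = 0.433, range 1.98e-07 to 0.433) were not; with 30 alone 22 were. The count was 131 without coated M number 1, 13 without coated 2, 18 without coated 3, 8 without coated 4, 12 without uncoated 1, 12 without uncoated 4 and 2 without uncoated 5. Of the 16 named genes called, Itgb7 and Rasgrp2 passed whichever sample was left out.

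The coating effect on DC-activated cells differed between day 4 and day 3 in S phase genes and in single genes of other kinds. Gzmb had a coating effect larger at day 4 by log2 2.28 ± 0.54 (adjusted p = 0.0355), the interferon-induced membrane protein Ifitm1 by 2.96 ± 0.49 (adjusted p = 0.00508) and Il2ra by 1.74 ± 0.46 (adjusted p = 0.0458). The effect was more negative at day 4 for Ccr7 (log2 -1.89 ± 0.39, adjusted p = 0.021), Tcf7 (-2.26 ± 0.59, adjusted p = 0.0492) and Nsg2 (-3.45 ± 0.76, adjusted p = 0.021). Of 37 S phase genes 25 had a higher effect at day 4 and 0 a lower one (35 and 0 adjusted over the list alone; camera 2.58e-25, adjusted p = 0.0141 with an estimated correlation). Of 21 naive and memory genes 6 had a lower effect (8 adjusted over the list alone; camera 3.5e-08, adjusted p = 0.156 with an estimated correlation).

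Of 9794 genes tested for this difference between days, 225 were higher and 135 lower at day 4; M numbers differ between the days, so day and set of samples are confounded. With M number as a block Gzmb had log2 2.00 (adjusted p = 0.0951, range over its alternatives 0.00261 to 0.0951) and Tcf7 -2.33 (adjusted p = 0.0704, range 0.0051 to 0.121), so neither was called. The count was 142 without coated M number 2 of day 3, 212 without coated 4, 179, 119 and 115 without uncoated 1, 4 and 5. At day 4 it was 140 without coated 6, 116 without coated 7, 185 without uncoated 6, 197 without uncoated 9 and 192 without uncoated 10. Of the 10 named genes called, 5 passed whichever sample was left out: Ifitm1, Fam20a, Igfbp7, Tagap and Ccr7. Il2ra lost its call in 16 of 18 such fits, Tcf7 in 15 and Gzmb in 11.

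Bead-activated cells at day 3 on the coating differed in few genes. Pck2, a mitochondrial enzyme of the phosphoenolpyruvate pathway, had 39.6 ± 8.83 CPM (SD, n = 5) in coated and 12.9 ± 1.72 CPM (n = 3) in uncoated cells (log2 1.63 ± 0.26, adjusted p = 0.0276). The cholesterol synthesis enzyme Hmgcs1 rose by 0.97 ± 0.17 (adjusted p = 0.0434) and the lactate exporter Slc16a3 by 0.90 ± 0.15 (adjusted p = 0.029). The chemokine Xcl1 fell by 1.68 ± 0.27 (adjusted p = 0.0276), and the MHC class II genes Cd74 and H2-Aa fell by 1.95 ± 0.28 (adjusted p = 0.0171) and 2.26 ± 0.31 (adjusted p = 0.0117). Gzmb had log2 -0.30 ± 0.18 (adjusted p = 0.559) and Ifng -1.91 ± 0.34 (7.99 ± 3.8 against 30.5 ± 1.91 CPM, adjusted p = 0.0542, where the authors' adjusted p is 0.00376). Ifng was called with M number as a block (log2 -1.74, adjusted p = 0.0188, range over its alternatives 0.00205 to 0.421).

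Of 22 cholesterol biosynthesis genes at bead day 3, all 22 were positive and 1 rose (4 adjusted over the list alone; median log2 0.45, camera 1.34e-08, adjusted p = 0.256 with an estimated correlation). Of 19 hypoxia response genes 17 were positive and 0 were called (4 rose adjusted over the list alone; camera 1.48e-05, adjusted p = 0.0991 with an estimated correlation). Of 20 glycolysis genes 1 rose (1 adjusted over the list alone; camera 0.000594, adjusted p = 0.153 with an estimated correlation). The 37 S phase genes had a median of 0.00 and 0 calls (0 adjusted over the list alone; camera 0.969). Of 6 MHC class II genes 2 fell (4 adjusted over the list alone; camera 0.00746, adjusted p = 0.2 with an estimated correlation), with summed transcripts of 128 ± 12.6 CPM in coated and 191 ± 25.8 CPM in uncoated cells. The 7 tested mitochondrially encoded transcripts were all negative with 0 calls (5 fell adjusted over the list alone; camera 1.48e-05, adjusted p = 0.353 with an estimated correlation), their sum being 253 ± 118 against 654 ± 365 CPM.

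In all, 4 genes rose and 5 fell of 8985 tested at bead day 3, and 1013 had an unadjusted p under 0.05, where chance gives 449; the authors' table calls 4, of which 0 are shared. Gapdh was under 100 CPM in all 3 uncoated libraries and in 1 of 5 coated ones. What sets the Gapdh level thus cannot be told apart from the coating here. None of the 6 named genes called passed in every fit that left out 1 sample. The count was 6 without coated M number 1 and 6 without coated 4, 25 without coated 3, 5 without uncoated 1, 2 without uncoated 2, and 0 in edgeR without uncoated 4, where 621 of 9378 genes had an unadjusted p under 0.05 (469 by chance) and DESeq2 called 7. With all groups in 1 fit Cd74 (log2 -1.93, adjusted p = 0.403, range over its alternatives 1.24e-05 to 0.403) and H2-Aa (adjusted p = 0.558, range 5.23e-05 to 0.558) were not called. The log2 fold change of H2-Aa ran from -2.44 to -2.03 over its alternatives.

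Most genes called in bead-activated cells at day 7 were lower on the coating, metallothioneins and immediate early genes among them. Mt1 and Mt2, which bind zinc and other metals, fell by 2.48 ± 0.29 (40.4 ± 13.1 CPM, n = 4, against 227 ± 70.8 CPM, n = 5; adjusted p = 0.00296) and 3.05 ± 0.37 (adjusted p = 0.00506). The chemokine Ccl5 fell by 2.36 ± 0.32 (45.7 ± 10.4 against 235 ± 84.3 CPM, adjusted p = 0.00805). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose by 1.12 ± 0.20 (256 ± 57.3 against 118 ± 27.4 CPM, adjusted p = 0.0193). The granzyme Gzmm rose by 1.46 ± 0.31 (adjusted p = 0.0381) and Eomes, a transcription factor of effector and memory CD8 cells, by 0.90 ± 0.20 (adjusted p = 0.0463). Gzmb had log2 -0.54 ± 0.21 (2770.3 ± 417 against 4040.2 ± 1309.9 CPM, adjusted p = 0.156) and Ifng -0.04 ± 0.35 (adjusted p = 0.958).

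Of 37 S phase genes at bead day 7 all 37 were positive and 1 rose, the chromatin remodeller Hells by 1.00 (28 adjusted over the list alone; median log2 0.58, camera 1.35e-14, adjusted p = 0.362 with an estimated correlation). Of 40 genes of G2 and M phase 39 were positive and 1 rose, Birc5 (survivin) by 0.58 (2 adjusted over the list alone; camera 2.78e-07, adjusted p = 0.415 with an estimated correlation). Of 16 immediate early genes 7 fell and 0 rose (11 adjusted over the list alone; camera 6.69e-09, adjusted p = 0.252 with an estimated correlation), with the mRNA decay factor Zfp36 at -1.27 (adjusted p = 0.00231) and the antiproliferative Btg2 at -1.54. Of 30 interferon response genes 1 fell, Irf9 by 1.08 (15 adjusted over the list alone; camera 3.71e-06, adjusted p = 0.415 with an estimated correlation). Of 16 amino acid stress genes 2 fell, Ddit3 by 1.69 and Trib3 by 1.49 (5 adjusted over the list alone; camera 0.0232, adjusted p = 0.443 with an estimated correlation). Of 17 p53 targets and apoptosis genes 2 fell, the pro-apoptotic Bbc3 by 1.71 and Bcl2l11 by 1.32 (5 adjusted over the list alone; camera 0.00318, adjusted p = 0.415 with an estimated correlation). Of 11 chemokines and their receptors 1 fell (4 adjusted over the list alone; camera 0.003, adjusted p = 0.312 with an estimated correlation).

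Summed markers of other cells were also higher in some uncoated libraries at bead day 7. Summed macrophage markers were 483 ± 347 against 136 ± 95.8 CPM and summed erythroid ones 275 ± 373 against 14.4 ± 2.73 CPM. The erythroid ones lay in uncoated M numbers 3 and 4 (496 and 829 CPM), the other 3 having 11.6 to 19.7 CPM. The macrophage ones ran from 61 to 985 CPM among uncoated libraries and did not follow the erythroid ones. Their highest value, 985 CPM, was in 1 of those other 3, where MHC class II transcripts summed to 69.4 to 91.2 CPM. In M numbers 3 and 4 these summed to 258 and 548 CPM. The macrophage sum therefore need not come from macrophages. Of the 4 macrophage markers tested 1 fell, Fcer1g by 2.60 (2 adjusted over the list alone; camera 0.00318, adjusted p = 0.312 with an estimated correlation). In all, 37 genes rose and 123 fell of 8696 tested; the authors' table calls 850, of which 145 are shared with the same direction. Without uncoated M numbers 3 and 4, which lie nearest to day 0, 37 genes were called and Ccl5 was not (adjusted p = 0.105, range over its alternatives 2.12e-12 to 0.105). With M number as a block Eomes (log2 0.92, adjusted p = 0.0642, range 0.00226 to 0.223), Ddit3 (-1.56, adjusted p = 0.068, range 6.64e-06 to 0.151) and Irf9 (-0.96, adjusted p = 0.0895, range 8.09e-05 to 0.196) were not called. The count was 27, 31, 48 and 20 without coated M number 1, 2, 3 and 5, and 809, 551, 42, 78 and 40 without uncoated 1, 2, 3, 4 and 5. Of the 24 named genes called, 6 passed in each of these fits: Mt1, Mt2, Bbc3, Zfp36, Btg2 and Fcer1g.

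The coating effect on bead-activated cells differed between day 7 and day 3. It was larger at day 7 for Gclm (log2 1.78 ± 0.29, adjusted p = 0.0054) and the histone gene H4c2 (1.63 ± 0.37, adjusted p = 0.0263). It was more negative for Ccl5 (-3.78 ± 0.91, adjusted p = 0.0389), the cholesterol sulfotransferase Sult2b1 (-3.40 ± 0.75, adjusted p = 0.0275) and the inhibitory receptor Lag3 (-1.85 ± 0.49, adjusted p = 0.0416). Of 37 S phase genes 2 had a higher effect and 0 a lower one (15 and 0 adjusted over the list alone; camera 2.31e-09, adjusted p = 0.478 with an estimated correlation). Of 19 hypoxia response genes 4 had a lower effect (12 adjusted over the list alone; camera 6.23e-06, adjusted p = 0.0667 with an estimated correlation). With M number as a block H4c2 (log2 1.59, adjusted p = 0.0667, range over its alternatives 0.0085 to 0.0827), Ccl5 (-3.47, adjusted p = 0.12, range 0.000944 to 0.12) and Lag3 (-1.71, adjusted p = 0.0909, range 0.0114 to 0.0971) were not called. At day 3 Gapdh was under 100 CPM in all 3 uncoated libraries and in 1 of 5 coated ones. What sets the Gapdh level cannot be told apart from the coating at that day. Of 9481 genes tested, 143 had a higher and 240 a lower effect. The count was 87 with M number as a block, 191, 151, 69, 74 and 92 without coated 1 or 5 or uncoated 1, 2 or 4 of day 3. For day 7 it was 118, 195, 113, 888, 857, 145, 214 and 162 without coated 1, 2 or 5 or uncoated 1, 2, 3, 4 or 5. Gclm passed in every fit that left out 1 sample.

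At day 3 the coating effect differed between DC- and bead-activated cells in a set of genes that included Ifng and Pck2. The effect was higher with DCs for Ifng (log2 2.32 ± 0.35, adjusted p = 0.00573), for Rgs16, which dampens G protein signalling, (2.69 ± 0.39, adjusted p = 0.00199), Ccl3 (2.38 ± 0.49, adjusted p = 0.0342) and the cell cycle inhibitor Cdkn1a (1.72 ± 0.37, adjusted p = 0.0377). It was lower with DCs for Pck2 (-2.47 ± 0.39, adjusted p = 0.00573), Rasgrp2 (-2.03 ± 0.24, adjusted p = 0.000356) and the fatty acid desaturase Fads2 (-2.65 ± 0.55, adjusted p = 0.0348). Of 22 cholesterol biosynthesis genes 0 were positive and 1 was called (11 lower adjusted over the list alone; camera 2.17e-07, adjusted p = 0.221 with an estimated correlation). Of 21 hypoxia response genes 1 was lower (11 adjusted over the list alone; camera 9.02e-07, adjusted p = 0.183 with an estimated correlation). The effects on Gzmb differed by log2 0.20 ± 0.40 (adjusted p = 0.826). That value ran from 0.05 to 1.15 over its alternatives (adjusted p 0.0661 to 0.959), so a larger difference is not excluded.

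Of 10075 genes tested for this difference, 31 were higher and 73 lower with DCs. Coated and uncoated DC sums mixed the libraries with 30 and 120 unequally, so this difference is partly confounded with that number. In the bead arm Gapdh was under 100 CPM in all 3 uncoated libraries and in 1 of 5 coated ones. What sets the Gapdh level cannot be told apart from the coating in that arm. The count was 58 with all groups in 1 fit, 41 with single DC libraries, 18 with 120 and 9 with 30 alone. It was 343 and 54 without coated bead M number 3 or 5, and 39, 19 and 13 without uncoated bead 1, 2 or 4. It was 170, 32, 66 and 36 without coated DC 1, 2, 3 or 4, and 63, 163 and 16 without uncoated DC 1, 3 or 5. Ifng, Rgs16, Pck2 and Rasgrp2 passed whichever sample was left out, but with all groups in 1 fit Rgs16 had an adjusted p of 0.115 (range over its alternatives 4.57e-06 to 0.115). The log2 difference of Rgs16 ran from 2.31 to 3.03 over these alternatives. Ccl3 was not called with M number as a block (log2 2.26, adjusted p = 0.069, range over its alternatives 0.00023 to 0.228). With 120 alone Rasgrp2 had an adjusted p of 0.108 (range over its alternatives 7.07e-11 to 0.108), and with 30 alone Pck2 had 0.105 (range 1.27e-05 to 0.105).

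**Figure D3:**
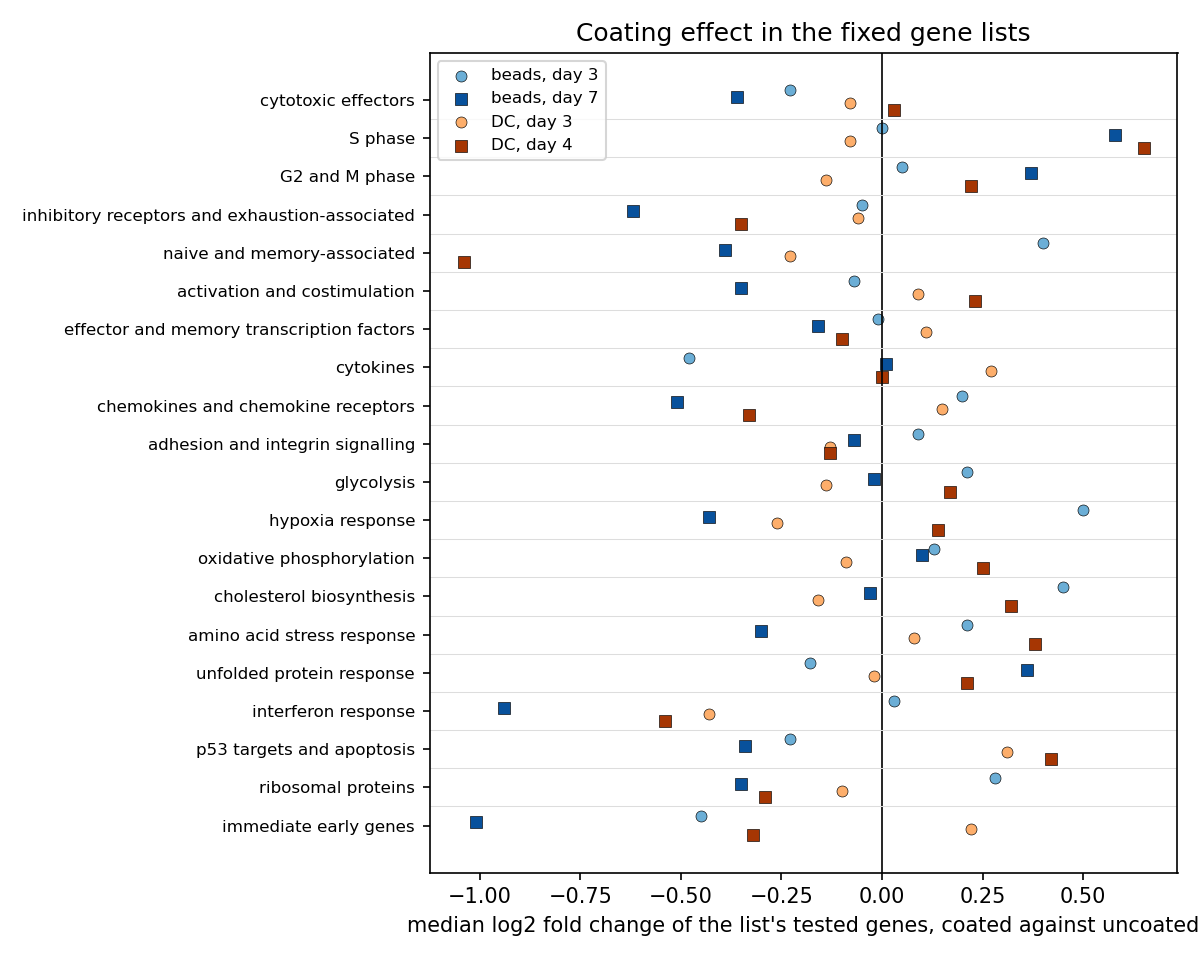
Median log2 fold change, coated over uncoated (x axis), of the tested members of each of 20 gene lists (y axis) in the 4 coating comparisons (points, by comparison). The S phase list has a median of 0.65 at DC day 4, 0.58 at bead day 7, -0.08 at DC day 3 and 0.00 at bead day 3, and the naive and memory list -1.04 at DC day 4.

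Without the coating, DC- and bead-activated cells differed widely at day 3. The inhibitory receptor Pdcd1 had 289.8 ± 22.4 CPM (SD, n = 4) with DCs and 18 ± 2.02 CPM (n = 3) with beads (log2 3.99 ± 0.15, adjusted p = 1.29e-10). Lag3 was higher by 2.32 ± 0.16 and Ifng by 2.62 ± 0.19 (189 ± 44.3 against 30.6 ± 1.85 CPM, adjusted p = 3.75e-07). Prf1 was higher with DCs by 2.27 ± 0.20 and Gzmb was lower, at log2 -1.18 ± 0.12 (2277 ± 357 against 5143 ± 577 CPM, adjusted p = 9.05e-06). Eomes was at log2 -6.17 ± 0.18 (4.54 ± 1.69 against 375 ± 64.5 CPM, adjusted p = 1.59e-11) and Ifitm1 at -4.36, while the chemokine receptor Ccr6 was higher, with 40 ± 3.8 against 0.206 ± 0.357 CPM. So near 0 its log2 fold change is loose, at 6.77 with all samples and 9.80 without uncoated bead M number 1. Of 27 interferon response genes 23 were lower with DCs (23 adjusted over the list alone; camera 1.04e-11, adjusted p = 0.119 with an estimated correlation). Of 12 inhibitory receptors and exhaustion genes 9 were higher and 2 lower (10 and 2 adjusted over the list alone; camera 4.33e-06, adjusted p = 0.119 with an estimated correlation). Among the 9 marker lists, natural killer markers summed to 12.7 ± 3.78 CPM with DCs and 389 ± 72.0 CPM with beads, and the 2 tested were lower, Eomes being 1 of them. Eomes, also a factor of effector and memory CD8 cells, had 375 ± 64.5 CPM with beads, scaled within this comparison. The sum is scaled over all samples, so Eomes may make up most of it, but its exact share is not given. The sum therefore need not come from natural killer cells. Of 7 DC markers 5 were higher with DCs and 1 lower (5 and 1 adjusted over the list alone; camera 0.00286, adjusted p = 0.24 with an estimated correlation), summing to 1171.6 ± 94.8 against 697.8 ± 76.3 CPM. The DC list also holds Ccr7, listed with naive and memory T cell genes too, so its rise need not come from DCs. Summed MHC class II transcripts were 206 ± 70.5 CPM with DCs and 191 ± 25.8 CPM with beads, and 209 ± 70.6 and 128 ± 12.6 CPM on the coating.

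With the coating the same comparison gave Ifng 4.95 ± 0.23 higher with DCs (248 ± 30.5 CPM, n = 5, against 7.96 ± 3.77 CPM, n = 5; adjusted p = 3.45e-09). Pdcd1 was 4.94 ± 0.20 higher and the costimulatory receptor Tnfrsf4 5.53 ± 0.20 (774 ± 51.5 against 17 ± 6.88 CPM). Lower genes were Eomes, at log2 -6.51 ± 0.35, and Ifitm1 at -5.72 ± 0.32. Of 26 interferon response genes 24 were lower with DCs (25 adjusted over the list alone; camera 4.44e-15, adjusted p = 0.0435 with an estimated correlation). Of 16 activation and costimulation genes 11 were higher and 2 lower (11 and 2 adjusted over the list alone; camera 0.00016, adjusted p = 0.0435 with an estimated correlation). Of 17 p53 targets and apoptosis genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone; camera 2.81e-05, adjusted p = 0.0636 with an estimated correlation). Of 7 DC markers 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera 0.0242, adjusted p = 0.386 with an estimated correlation), summing to 1277.5 ± 201.9 against 749.1 ± 60.5 CPM.

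Without the coating 985 genes were higher and 1233 lower with DCs of 8907 tested, and with it 1748 and 1943 of 9258, or 2386 in all with the 120 libraries alone. Gzmb on the coating, at log2 -0.97 ± 0.30 (adjusted p = 0.0303), was at 0.11 with the 30 or 120 of the title as a covariate and at 0.13 in the 120 libraries alone (adjusted p = 0.674, range over its alternatives 8.94e-06 to 0.739). It was at -1.03 and not called with M number as a block (adjusted p = 0.117). Gzmb without the coating was at -0.77 in the 120 libraries alone and -3.03 in the 30 libraries alone. Il2ra without the coating, at 0.54 ± 0.13 (adjusted p = 0.00604), was at -0.06 in the 30 libraries alone (adjusted p = 0.822, range 0.000512 to 0.822).

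In uncoated activated cells of every kind and day, Gzmb and most S phase genes rose from day 0 and most naive and memory genes fell. Gzmb rose from 59.1 ± 10.6 CPM (SD, n = 9) to 4415 ± 519.6 CPM (n = 3) with beads at day 3 (log2 6.20 ± 0.14). It rose by 5.93 ± 0.18 at bead day 7, 5.11 ± 0.13 at DC day 3 and 1.13 ± 0.13 at DC day 4. Il2ra rose by 5.51 ± 0.29 at bead day 3, 5.06 ± 0.33 at bead day 7 and 6.15 ± 0.26 at DC day 3, and was too low to be tested at DC day 4. Ccr7 fell in all 4 (log2 -3.34 ± 0.24, -3.42 ± 0.24, -2.63 ± 0.19 and -2.21 ± 0.17 in that order), from 1963 ± 483 CPM at day 0. Pdcd1 rose by 6.57 ± 0.26 at DC day 3 and 3.06 ± 0.36 at DC day 4, and Lag3 by 4.52 ± 0.22 and 5.65 ± 0.26. Prf1 fell by 1.36 ± 0.22 at bead day 3 and by 1.72 ± 0.17 at DC day 4, and rose by 1.01 ± 0.16 at DC day 3. Each of these had an adjusted p under 0.05. At bead day 7 Prf1 had log2 -0.08 ± 0.21 (adjusted p = 0.76).

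Of the tested S phase genes 36 of 37 rose at bead day 3, 33 of 35 at bead day 7, 37 of 37 at DC day 3 and 34 of 36 at DC day 4 (36, 34, 37 and 34 adjusted over the list alone). For the naive and memory list 19, 17, 17 and 15 of 22 fell (20, 17, 18 and 15 adjusted over the list alone). For S phase the adjusted p was 0.0128, 0.114, 0.0211 and 0.0188 with an estimated correlation, and for the naive list 0.0106, 0.114, 0.0211 and 0.0188. At DC day 3, 18 of 20 glycolysis and 19 of 21 cholesterol biosynthesis genes rose (18 and 19 adjusted over the list alone; adjusted p = 0.0301 with an estimated correlation for both).

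Day 0 libraries also held transcripts of other spleen cells. Summed erythroid markers were 59644.5 ± 35763 CPM (n = 9), summed MHC class II transcripts 15161 ± 3119 CPM and summed macrophage markers 1426 ± 499.8 CPM. All 16 B cell, 7 erythroid and 9 MHC class II genes tested fell in each of the 4 comparisons (16, 7 and 9 adjusted over the list alone; camera 3.83e-05 for the erythroid list at bead day 3, adjusted p = 0.141 with an estimated correlation). At bead day 3 the hemoglobin gene Hbb-bt fell by 11.38 ± 1.03, a loose value that ran from log2 -12.58 to -10.72 when 1 sample was left out. Alas2, an enzyme of heme synthesis in red cells, had 509 ± 309 CPM at day 0 and no count in the 3 bead libraries, at least 624-fold lower. The complement gene C1qa was at least 145-fold lower (floor 0.815 CPM, 3 counts over the group).

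Against day 0, 2681 genes rose and 3114 fell of 8891 tested at bead day 3, 2828 and 2878 of 9281 at bead day 7, 3425 and 3528 of 9259 at DC day 3, and 2472 and 2739 of 9365 at DC day 4.

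Libraries of DC day 3 with 120 in their title differed from those with 30 in cytotoxic and metabolic genes. Gzmb had 3713 ± 1141 CPM (SD, n = 8) with 120 and 942 ± 319 CPM (n = 8) with 30 (log2 2.10 ± 0.08, adjusted p = 2.52e-12). Selp rose by 3.12 ± 0.16 and Tg, the thyroglobulin gene, by 2.64 ± 0.13, while the chemokines Ccl4 and Xcl1 fell by 2.17 ± 0.09 and 2.44 ± 0.28. Of 20 glycolysis genes 15 rose and 0 fell (16 and 0 adjusted over the list alone; camera 1.24e-11, adjusted p = 0.0167 with an estimated correlation). Of 21 hypoxia response genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.0243 with an estimated correlation). Of 13 cytotoxic effector genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.049 with an estimated correlation). Of 7 DC markers 5 rose (6 adjusted over the list alone; adjusted p = 0.0167 with an estimated correlation). In all, 583 genes rose and 592 fell of 9631 tested; the count was 709 without uncoated M number 5.

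**Figure D4:**
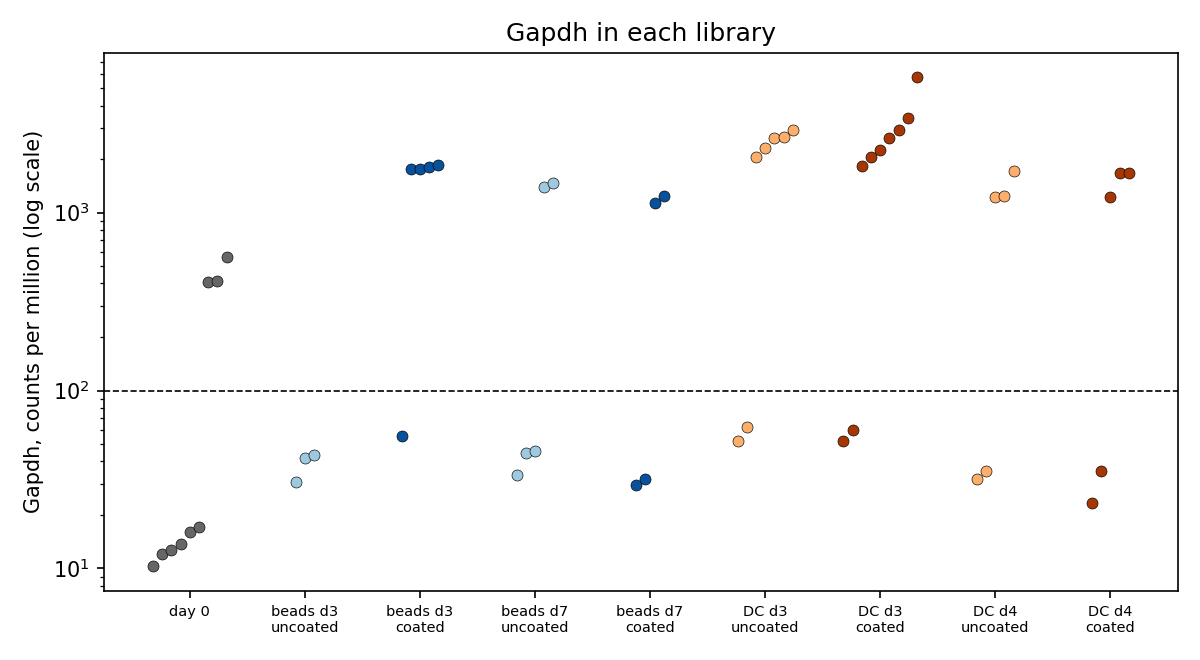
Gapdh expression of each library (y axis, CPM, log axis) by group (x axis); points are libraries and the dashed line marks 100 CPM. In 23 libraries Gapdh lies between 10.3 and 62.7 CPM and in the other 29 at 410 CPM or above.

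Positions of the genes discussed most are, in mm10: Gzmb on chromosome 14 (56258838 to 56262260, minus strand), Ifng on 10 (118441046 to 118445892, plus strand), Tcf7 on 11 (52252371 to 52283014, minus strand), Nsg2 on 11 (32000463 to 32059202, plus strand), Itgb7 on 15 (102215995 to 102231944, minus strand), Pck2 on 14 (55540266 to 55551242, plus strand), Cd74 on 18 (60803848 to 60812652, plus strand) and Mt1 on 8 (94179082 to 94180327, plus strand).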

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

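The tests on regrouped samples, on DC day 4 M number 8 and other cells, on bead day 3 and on Gapdh were chosen after the results were seen; the test of depth at DC day 4 was chosen before.

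In 88 groups of 4 to 10 values of 10 genes and of library totals, 7 values lay far from the others of their group, where chance gives about 1 in 20, or 4.4. Among them, Mki67 was 80.9 CPM in coated bead day 3 M number 3 (others 196 to 264 CPM) and 169 CPM in uncoated DC day 4 M number 8 (others 281 to 324 CPM). Ifng was 20.6 CPM in the latter (others 9.31 to 9.82 CPM). Ccr7 was 549.6 CPM in coated DC day 3 M number 2 (others 314 to 339 CPM). Itgal was 343 CPM in coated bead day 3 M number 3 (others 250 to 274 CPM) and 267 CPM in coated DC day 3 M number 3 (others 193 to 207 CPM).

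The coating effects of 27 named genes differed between activations or days by a test of the difference itself. Between DCs and beads at day 3 they differed, as log2, by 2.69 for Rgs16, 2.38 for Ccl3, 2.32 for Ifng, 1.72 for Cdkn1a, -2.65 for Fads2, -2.57 for Itgb3, -2.47 for Pck2 and -2.03 for Rasgrp2. Between bead day 7 and day 3 they differed by 1.78 for Gclm, 1.67, 1.66 and 1.63 for the histone genes H3c1, H2ac11 and H4c2, -3.78 for Ccl5, -3.71 for Klhl30, -3.40 for Sult2b1, -3.30 for Pik3ip1 and -1.85 for Lag3. The value of Klhl30 ran from -8.09 (without uncoated day 3 M number 1) to -3.26 when 1 sample was left out, and its call was lost in 12 of 17 such fits. Between DC day 4 and day 3 they differed by 2.96 for Ifitm1, 2.28 for Gzmb, 2.02 for Fam20a, 1.88 for Igfbp7, 1.74 for Il2ra, -3.45 for Nsg2, -2.48 for the noncoding Rn7sk, -2.26 for Tcf7, -2.14 for Tagap and -1.89 for Ccr7.

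Regrouping the samples asks whether chance gives as many calls. For bead day 3 chance is not excluded: 3 of 56 splits called as many genes as the real 9, the highest of the others 304. For bead day 7 (160 genes, highest other 903) and DC day 3 (42, highest other 252) 3 of 100 splits did, the real one included, which is under the 5 in 100 asked. What sets apart the splits that call several times the real count was not tested. In the other comparisons 1 of 100 splits, the real one, called as many (1 of 35 for DCs against beads uncoated). No other split drawn reached the real count there. None of these shares was adjusted over the comparisons, so they argue against chance but do not exclude it. The real counts and the highest others were 1738 and 260 for DC day 4, and for the differences of DC and bead effects (104, 18), of bead days (383, 11) and of DC days (360, 195). For DCs against beads uncoated (2218, 146) and coated (3691, 1) the same held, as for the comparisons with day 0 (5795, 4; 5706, 3; 6953, 53; 5211, 2634 for beads at days 3 and 7 and DCs at days 3 and 4) and 120 against 30 (1175, 653). At DC day 4 the 11 other splits drawn that part all 5 pairs of libraries with 1 M number called 0 genes in edgeR.

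The 1738 genes of DC day 4 outnumber those of the other coating comparisons, and its libraries differ in depth. After every library was thinned to 1140327 counts 720 genes were still called, and without both libraries of M number 8, whose uncoated one stood apart, 1537, both above the highest other split, so the tables argue against either as the whole source. Other cells that magnetic selection of CD8+ cells left in uncoated wells would have to make up 36.1% of the RNA to give the median S phase change by dilution, and 86.5% for Gzmb. Summed MHC class II, erythroid and macrophage transcripts of the uncoated library highest in them (M number 8) were 10.5%, 1.99% and 13.5% of their day 0 levels. This argues against cells that carry these transcripts as the whole source. B cell markers, left out of that test, summed to 2286 ± 225 CPM in uncoated and 2296 ± 203 CPM in coated cells (6735 CPM at day 0). Their mean log2 CPM was 2.373 ± 0.784 in uncoated and 1.624 ± 0.358 in coated cells (7.262 at day 0). The near-equal sums therefore do not show an equal content of B cells. DC markers, also left out, summed to 929 ± 63.3 and 747 ± 83.2 CPM (3947 CPM at day 0). Cells without any of these markers, such as CD8+ T cells that stayed unactivated, are not covered, so the test cannot decide on them. Any difference in how the wells were handled stays open, untested, as does the coating itself as a biological source.

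In bead cells at day 3, 11 of 13 MHC class II and mitochondrially encoded genes were negative. The uncoated library of M number 2 has the fewest counts of the bead libraries. Summed MHC class II transcripts were 205.4 CPM or above in the other uncoated libraries and 141 CPM at most in coated ones, which argues against that library as their source. For mitochondrially encoded transcripts it stays open: M number 2 had 1044.3 CPM and the others 322.1 and 596 CPM, where coated libraries reached 420.2 CPM. A count of signs without M number 2, used before, could hardly have come out otherwise and was dropped. Cells left from day 0 could bring MHC class II transcripts into uncoated wells. Magnetic selection of CD8+ cells should remove such cells, but day 0 libraries still held 15161 CPM of these transcripts. The erythroid, macrophage and B cell markers had medians of -1.14 (2 genes), -0.35 (3 genes) and -0.01 (3 genes), so the values do not decide and this stays open, and so does a change of the T cells themselves on the coating.

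Gapdh, a glycolytic gene often used as a reference, lay at 10.3 to 62.7 CPM in 23 libraries and at 410 CPM or above in 29. Every group had libraries at either level but uncoated bead day 3, where all 3 were low. Of the 5 coated bead libraries of day 3, 4 were high. What sets the level therefore cannot be told apart from the coating at bead day 3. It bears on both differences of coating effects that use bead day 3, and on uncoated DCs against beads too. For uncoated DCs against beads Gapdh was called at log2 5.43 (adjusted p = 0.0483), a call lost in 6 of 7 fits that left out 1 sample. Reads assigned to its 116 annotated copies argue against copies as the source: Gapdh and the 86 copies in the table together reached the lowest level of the other libraries after day 0 (1139 CPM) in 1 of 17 low ones. An earlier criterion, which asked for 1 such library, had been met and was replaced after that was seen. Depth is argued against by 8 low libraries above the median total, and a variant carried by the source of an M number by 9 of 10 M numbers having both levels. Reads set aside in some libraries because they match several copies stay open, and no biological explanation was tested.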

How the results depend on the processing

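All alternatives but the libraries and genes left out by choice were fixed before the data were examined; those were chosen after. Of 5498 values of named genes under an alternative, 4856 kept their direction and side of the threshold, 591 no longer passed, 46 passed newly and 5 turned. Among these were Gzmb of coated DCs against beads (0.11 with the 30 or 120 of the title as covariate of single libraries, 0.13 with 120 alone), Gzmb of the DC day 3 coating effect (0.72 with that covariate) and Il2ra of uncoated DCs against beads (-0.06 with 30 alone). Of 1590 values of gene lists 1274 kept both, 242 no longer passed, 74 passed newly and 0 turned, and 168 of 394 lost their call with an estimated correlation. Size factors of DESeq2 moved no count by over 1.5 times, nor did any alternative but leaving out a sample for DC day 4, the difference of DC days, uncoated DCs against beads, the comparisons with day 0 and 120 against 30.

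The DESeq2 test called more: 52 genes at bead day 3, 577 at bead day 7, 112 at DC day 3, 333 for the difference of DC and bead effects and 625 for that of bead days. With M number as a block the counts in the same order were 99, 243, 141, 482 and 87. At DC day 4, where libraries with 1 M number deviated together, the block gave 2572 calls against 1738 without it. With all groups in 1 fit the counts were 986 at bead day 7, 27 at DC day 3, 58 for DCs and beads and 636 for bead days. Bead day 3 had 14 without a filter and 3 without M number 2, and bead day 7 had 37 without uncoated M numbers 3 and 4. With 120 alone DC day 3 had 8, the difference of DC and bead effects 18 and coated DCs against beads 2386; with 30 alone the first had 22 and the second 9, which had 41 with single libraries. The cause was not tested; leaving libraries out also leaves fewer samples.

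Leaving out 1 sample gave 0 to 25 genes at bead day 3 (beside the 0 of edgeR, 621 with an unadjusted p under 0.05 and 7 in DESeq2), 20 to 809 at bead day 7, 2 to 131 at DC day 3, 864 to 2052 at DC day 4, 13 to 343 for DCs and beads. It gave 69 to 888 for bead days, 115 to 502 for DC days, 1609 to 2242 and 3260 to 3694 for DCs against beads uncoated and coated, 5064 to 5809, 5367 to 5833, 6557 to 7306 and 4681 to 5541 against day 0, and 709 to 1237 for 120 against 30. The extremes of the coating comparisons came without uncoated M number 4 and coated 3 (bead day 3), coated 5 and uncoated 1 (bead day 7), uncoated 5 and coated 1 (DC day 3) and coated 7 and 10 (DC day 4). In counts simulated with the sample numbers, depth and dispersion of the bead comparison of day 3, a 2-fold change was recovered in 46.9% of genes. A 4-fold one was recovered in 100%, so changes near 2-fold can be missed there. These counts had the same dispersion of a gene in every sample and no outlying library. Larger changes can be missed in the real libraries: Ifng, at log2 -1.91 at bead day 3, was not called (adjusted p = 0.0542).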

Other observations

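The tests of relations between coating effects were chosen before their results were seen, but those without the uncoated libraries nearest to day 0 after; the genes named in the next paragraph were chosen after their values were seen.

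Bead cells at day 7 and DC cells at day 4, the later time of each activation, shared calls in both directions. Of 8362 genes tested in both, 19 were higher on the coating in both, where independent calls would share 3.22, 35 were lower in both (10.3) and 7 opposite (14.87). Both uncoated groups held libraries that lay nearer to day 0, which could give shared calls too. The overlap was not computed without those libraries. Genes higher in both included Gclm and Txnrd1, which serve glutathione and thioredoxin redox control (log2 1.12 and 0.67 at bead day 7, 0.54 and 0.84 at DC day 4), the histone gene H4c2 (1.43 and 0.98) and Asf1b, a histone chaperone (0.88 and 0.52). Genes lower in both included Ddit3 (-1.69 and -0.52) and Trib3 (-1.49 and -1.33), though other genes of their amino acid stress list rose at DC day 4 (7 of 15, with 2 lower; 9 and 2 adjusted over the list alone; camera 0.0882, adjusted p = 0.421 with an estimated correlation). Others lower in both were Btg2 (-1.54 and -0.90), Hbp1 (-1.99 and -0.86), Mxd1 (-1.97 and -1.07) and the cholesterol exporter Abcg1 (-2.58 and -1.51). DC cells of days 3 and 4 shared 5 higher genes (1.39 if independent), with Bax and Wnt10b among them, and 11 lower (1.98), with Itgb7, Rasa3 and Pik3r1.

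One hypothesis was that the coating keeps later cells nearer to the profile of day 3. Across genes, which are not independent replicates, the coating effect of DC day 4 went with the change from day 0 to DC day 3 (Pearson r = 0.62, Spearman rho = 0.66; as large in 3 of 126 splits, exact permutation p = 0.0238). These splits ignore the M numbers, though libraries with 1 M number deviated together at DC day 4. No value limited to splits that part every pair was computed for this relation. The effect of bead day 7 went with the change from day 0 to bead day 3 (r = 0.53, rho = 0.57; 6 of 126, p = 0.0476, exact permutation). Adjusted over the 9 relations computed, the p-values were 0.107 and 0.143, so the hypothesis may hold but is not shown. The uncoated libraries nearest to day 0, some of which hold transcripts of other cells, would give such correlations too. Without both libraries of DC day 4 M number 8 r was 0.58, and 1 of 35 splits was as large (unadjusted p = 0.0286, the smallest they can give), which argues against that pair as the whole source. Without uncoated bead day 7 M numbers 3 and 4 r fell from 0.53 to 0.35 (1 of 35, unadjusted p = 0.0286), so for beads these libraries stay open as a source of part of it. The effect of DC day 4 did not run along 120 against 30 (r = -0.12, rho = -0.16, exact permutation p = 0.54, adjusted 0.54).

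Between coating effects, that of bead day 7 and DC day 4 had r = 0.48 and rho = 0.54 (1 of 126 splits, exact permutation p = 0.00794, the smallest they can give, adjusted 0.0715). The others had r = -0.33 and rho = -0.33 (bead days 3 and 7, exact permutation p = 0.294, adjusted 0.378), -0.36 and -0.37 (bead and DC day 3, p = 0.175, adjusted 0.315), -0.26 and -0.27 (bead day 3 and DC day 4, p = 0.389, adjusted 0.438), 0.20 and 0.20 (bead day 7 and DC day 3, p = 0.167, adjusted 0.315), and 0.23 and 0.22 (DC days 3 and 4, p = 0.286, adjusted 0.378). None was under 0.05 after adjustment, which does not show that the effects are unrelated. For bead day 7 and DC day 4 the highest other split also had an absolute r of 0.48 after rounding. That relation was not computed without the uncoated libraries nearest to day 0.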
